A study of Mus musculus with 10 samples.

How the data were processed

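Gene expression was measured in mouse acute lymphoblastic leukaemia cells recovered from the marrow of transplanted animals, with 1 Affymetrix array for each of 10 animals. Per the labels, the leukaemia carried human p210 bcr/abl and lacked the Ink4a/Arf locus, and it was given together with donor marrow and spleen cells to irradiated C57BL/6 recipients that had also received 5-fluorouracil. Donor cells were syngeneic (C57BL/6) for 5 samples and allogeneic (C3.SW) for the other 5. Leukaemia cells were recovered by flow cytometry every 2 to 3 weeks and moved to newly transplanted recipients, and RNA was taken after 3 such transplants. Per the labels' protocols, the final cells were sorted on green fluorescent protein straight into Trizol, and biotinylated cDNA was made from total RNA with NuGEN kits. Each sample is described as coming from its own animal. Whether the animals of a group shared leukaemia from the same earlier recipient is not given in the sources used here. The titles of allogeneic samples 4 and 5 share a leading number. Those of allogeneic samples 1, 2 and 4 share a trailing number, as do those of 3 and 5. The meaning of these numbers is not stated, so the p-values measure the spread between these animals.

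The deposited table holds 1 linear intensity per probe set and array for 45101 probe sets, and the authors' summarisation, scaling and filters are not given in the sources used here. The deposited intensity values ran from 0.74 to 22385, and between 361 and 461 probe sets per array stood at exactly 1. Median intensity lay between 53.3 and 72.1. The lower quartile was 18.7 to 19.5 on the arrays of allogeneic animals 1, 3 and 4 and 13.8 to 14.4 on the remaining 7, so the arrays were not on a common distribution. Under the design fixed before the data were examined, the values were therefore put on the log2 scale and quantile normalized between arrays. Quantile normalization had been listed beforehand as an alternative to the deposited scale, and the log2 values without it became the alternative instead.

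Probe sets were named with the platform annotation, with symbols updated by gene identifier to those of the GRCm38.p6 annotation for 34754 probe sets. There were 34945 probe sets with 1 symbol, 932 with several, 9160 with none and 64 controls. Each gene was represented by its probe set of highest mean over the 10 arrays, which left 18193 genes, and no filter on low values was applied. A background limit was set for each array, after the data had been seen, as the 95th percentile of 27 probe sets for bacterial transcripts that are not spiked in. It lay between 4.50 and 5.32 on the log2 scale. A gene at or below the limit on all 5 arrays of a group was treated as not well above background there. Its difference is given as at least N-fold, from the brighter group's mean against the dimmer group's mean of the higher of the limit and the gene's own value. Between 11224 and 13094 genes per array exceeded the limit, and the number of arrays limits the precision of every estimate.

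Groups were compared with limma (lmFit and eBayes, default settings), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of single genes come from limma. The genes named were the 12 with the largest rise and the 12 with the largest fall among called genes whose allogeneic values all lay above, or all below, the syngeneic values. Up to 4 members per list with the smallest p, the marker of highest array signal in each cell type list and the genes named by the labels were also eligible. Named outside this rule, after their values were seen, were further list members that passed, and Cdkn2b, H2-K1, H2-D1, Rsad2, Stat2 and the genes of the closing section that are in neither group. The 31 gene lists, 21 of cellular programmes and 10 of cell type markers, were fixed beforehand and held 554 genes, of which 497 were measured. They were tested 2-sided with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Whole-profile separation was tested 1-sided with an exact permutation test over the 126 splits into 5 and 5 samples, on mean between-group minus mean within-group Euclidean distance. Analyses used R 4.3.3, limma 3.58.1 and statmod 1.5.0.

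The gene and list tests were tested on simulated data of 18193 genes for the allogeneic against syngeneic comparison of 5 against 5, in 5 runs with 200 changed genes each. They recovered 89.6% of genes raised by 2 on the log2 scale, 89.2% at a log2 change of -2, 59.2% at 1 and 55.2% at -1. Of the calls, 5.85% were false. The shifted list was called in 5 of 5 runs, and 0 unshifted lists were called. Simulated genes varied independently, so false list calls that come from correlation between genes could not appear. Each gene had the same SD in both groups, and changed genes were drawn from outside the lower 25% by mean level.

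Alternatives covered the choice of probe set, filters on low values, normalization, the eBayes settings, array weights, the animal number as a block, thresholds, other list tests, other distances and leaving out each array. Added after the data were seen were 32 added to each value before log2, genes at background left out, the 3 arrays of raised low end left out, and log2 values without quantile normalization. No 2 arrays were copies, since at most 28 of the 45101 probe sets had identical values, other than values of exactly 1, in a pair. There were 10455 genes above background on every array. The human fusion transcript, probe sets with no or several symbols, and genome coordinates were not analysed here beyond what is stated.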

Results

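The data were 10 expression profiles of sorted leukaemia cells, 5 from animals given syngeneic donor cells and 5 from animals given allogeneic donor cells. The question was how leukaemia that had passed through an allogeneic immune environment differed from leukaemia passed through a syngeneic one. Between 11224 and 13094 of 18193 genes were above background on each array. Ratios of 3' to 5' Gapdh control probe sets, a sign of RNA integrity, were 1.46 to 1.56 in syngeneic and 1.38 to 1.59 in allogeneic samples.

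Genes named by the labels were examined first. Cdkn2a, the gene of the deleted Ink4a/Arf locus, was not well above background on any of the 5 syngeneic arrays and exceeded the limit on 1 allogeneic array, with means of 4.53 and 4.24 on the log2 scale. Its neighbour Cdkn2b, which encodes another cyclin-dependent kinase inhibitor, was well above background in both groups (8.68 and 9.04). Mouse Abl1 and Bcr differed by 0.030 (SE 0.19) and -0.047 (SE 0.18) on the log2 scale and did not pass the test. These probe sets were designed for mouse transcripts, and the human fusion was not analysed here.

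Interferon-inducible genes were higher in leukaemia from allogeneic recipients. Iigp1, an interferon-inducible GTPase that acts against intracellular pathogens, rose by 7.56 on the log2 scale (SE 0.41, 5 animals per group, adjusted p = 8.88e-05), and Gbp6, a guanylate-binding protein, rose by 5.73 (SE 0.40, adjusted p = 0.000233). Iigp1 exceeded background on 1 of 5 syngeneic arrays, and its log2 change ran from 6.12 to 7.83 over the other settings. The neighbouring GTPase gene Gm4951 was at least 37.2-fold higher (adjusted p = 0.000233). Across the genome 92 genes rose and 14 fell by limma. The 5 allogeneic values of each lay wholly above or wholly below the 5 syngeneic ones. This lack of overlap comes from the same values as the calls and is not separate support for them. Falls were fewer and included Egln3, an oxygen-sensing prolyl hydroxylase, which was at least 3.24-fold lower (adjusted p = 0.0120).

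Of the remaining 9 of the 12 largest rises, 4 were members of the type I interferon response list (Oas3, Oasl2, Rtp4 and Zbp1). The oligoadenylate synthetase gene Oas3 rose by 3.35 on the log2 scale (SE 0.35), Oasl2 by 2.91 (SE 0.48) and Rtp4, which encodes a receptor transporter protein, by 3.14 (SE 0.35). Zbp1, a sensor of Z-form nucleic acids, rose by 3.06 (SE 0.27), and Lgals3bp, a secreted galectin-binding protein, by 3.26 (SE 0.24). Plaat3, a phospholipase and acyltransferase, rose by 2.79 (SE 0.22), and Ifit1bl1, a relative of Ifit1, by 2.68 (SE 0.26). Batf2, a transcription factor, was at least 5.19-fold higher and BC023105 at least 1.92-fold higher. Adjusted p-values of these 9 genes ran from 0.000302 for Lgals3bp to 0.0300 for Oasl2. Some of the other large values also started near background, since Oas3 exceeded the limit on 1 of 5 syngeneic arrays, Oasl2 on 3 and Gbp6 on 4.

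**Figure D1:**
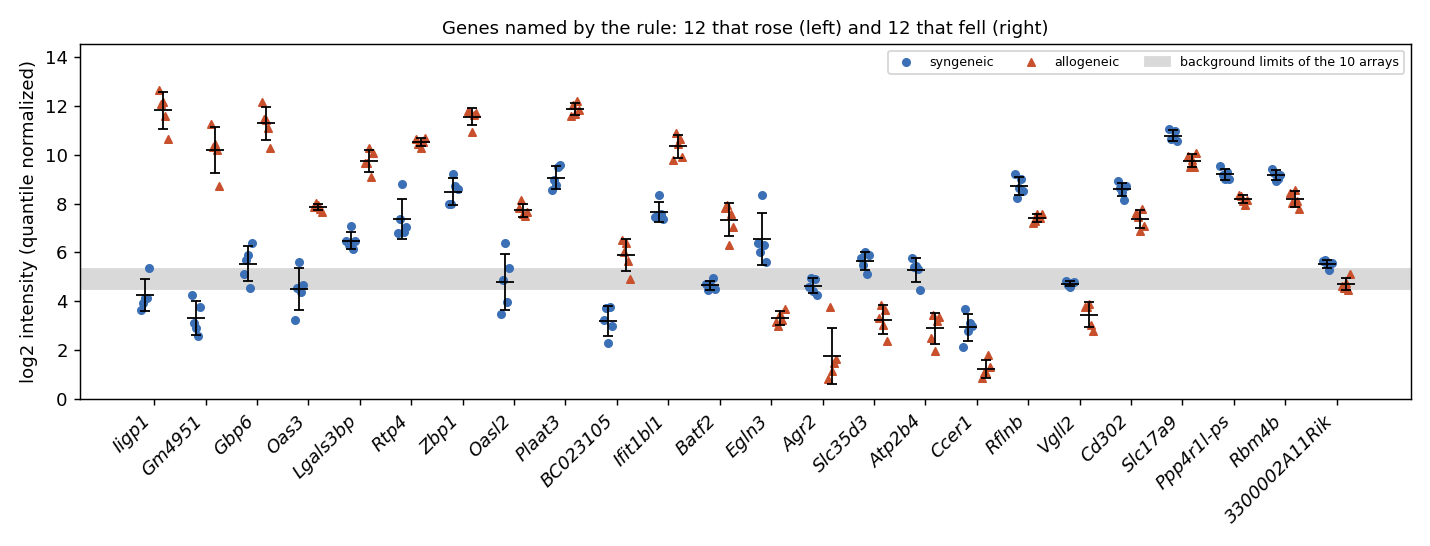
Log2 intensity after quantile normalization of the 24 genes named by rule, with 1 point per animal (circles for syngeneic, triangles for allogeneic, 5 each) and black bars for the mean and SD of each group; the grey band spans the background limits of the 10 arrays, 4.50 to 5.32. Iigp1 had means of 4.25 and 11.81, and Ccer1, which fell, lay below the band in both groups (2.95 and 1.23).

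Of 18 measured members of the interferon-gamma response list, 8 rose and 10 did not pass, and 12 rose when adjusted over the list alone. Besides Iigp1 and Gbp6, the examples were Gbp2 (2.14, SE 0.16, adjusted p = 0.000302) and Irf1, a transcription factor that drives antigen presentation genes (1.71, SE 0.14, adjusted p = 0.000515). Igtp, Irgm1, Irgm2 and Ifi47, all interferon-inducible GTPase genes, made up the rest, with log2 changes of 2.00, 1.51, 1.98 and 0.76. The list's median log2 change was 0.77 and its adjusted p by camera was 2.06e-14, or adjusted p = 0.0326 with an estimated correlation. Of 22 measured members of the type I interferon response list, 7 rose and 15 did not pass, and 13 rose when adjusted over the list alone. They were Zbp1, Oas3, Rtp4, Oasl2, the RNA sensor gene Ifih1 (1.45, SE 0.16), Oasl1 (1.60) and Bst2 (1.37), which encodes the virus tether tetherin. This list's median was 0.99 with an adjusted p of 1.75e-14 by camera, but adjusted p = 0.0931 with an estimated correlation. All 22 members had a positive difference, including Rsad2 (0.18) and Stat2 (0.21), which were far from passing.

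Antigen presentation genes of MHC class I had smaller differences. Of 15 measured members 2 rose and 13 did not pass, and 9 rose when adjusted over the list alone. Psmb9, an immunoproteasome subunit, rose by 1.16 (SE 0.12, adjusted p = 0.00211) and Tap1, a subunit of the peptide transporter, by 0.93 (SE 0.15, adjusted p = 0.0309). Another probe set of Tap1 went the opposite way, and the mean over its probe sets differed by 0.12 (adjusted p = 0.775). The heavy chain genes H2-K1 and H2-D1 differed by 0.35 and 0.30 with adjusted p-values of 0.126 and 0.167, and 1 of the 4 probe sets of H2-K1 passed the test. The list's median was 0.28 with an adjusted p of 1.71e-06 by camera, or adjusted p = 0.0381 with an estimated correlation. MHC class II was not called (adjusted p = 0.509), and 0 of its 11 measured members rose or fell.

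Markers of macrophages and monocytes were measured beside these groups because the sort could hold other cells. The 19 markers had a median difference of 0.21 and an adjusted p of 0.262 by camera. Relative to the syngeneic mean the list's median stood at -0.33 in allogeneic animal 1 and between 0.35 and 0.68 in the other 4. Without allogeneic animal 1 it was 0.43 (adjusted p = 0.0107) by camera. The interferon-gamma response list stood at 0.84 in allogeneic animal 1 and between 0.82 and 0.93 in the other 4. Fcgr3, whose probe set had the highest mean signal of these markers over all 10 arrays, had means of 12.25 and 12.46, and Mpeg1 had 11.95 and 12.63. Stroma and endothelium markers had a median difference of 0.37 (adjusted p = 0.0754), with 13 of 15 positive, and the list passed under 4 of 17 other settings (lowest adjusted p = 0.00135, with fry). These markers were near background, with median levels of 4.02 in the syngeneic and 4.74 in the allogeneic group. Only 11 of the 15 exceeded the limit on any array. Dendritic cell markers differed by 0.47 (adjusted p = 0.211). The probe sets of highest mean signal in each list over all 10 arrays, which does not rank the transcripts, were those of Mgp (5.82 and 6.08) and Ccr7 (9.14 and 9.61). The T cell (adjusted p = 0.262), NK cell (0.211, but 0.00986 with fry), granulocyte (0.761), erythroid (0.672), megakaryocyte and platelet (0.761), mature B cell (0.211) and plasma cell (0.433) lists were not called by camera. No member of the 10 marker lists passed the test over all genes, where Gzma of the NK cell list differed by 1.06 (adjusted p = 0.0995).

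Among genes of recognition and killing by lymphocytes, single members passed and no list did by camera on all genes in the main setting. Cd86, a costimulatory ligand, rose by 1.17 (SE 0.16, adjusted p = 0.0120), and 19 of the 20 measured costimulatory and inhibitory ligands did not pass (list adjusted p = 0.153, but 0.0360 with fry and 0.0295 with the lower 50% of genes left out). Fas, a death receptor, rose by 1.36 (SE 0.11, adjusted p = 0.000390), and 16 of 17 measured death receptor and pro-apoptotic genes did not pass (list adjusted p = 0.433, but 0.0298 with fry). Serpinb9 and Serpinb6b, members of a serpin family that includes granzyme inhibitors, rose by 1.29 (SE 0.23, adjusted p = 0.0477) and 0.87 (SE 0.13, adjusted p = 0.0187), while 12 of 14 measured members of their list did not pass (list adjusted p = 0.909). The 5 measured NK receptor ligands gave no call (adjusted p = 0.672).

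The 20 MYC and ribosome biogenesis genes were lower as a list by camera, with a median log2 change of -0.17 and an adjusted p of 0.000267, but not with an estimated correlation (adjusted p = 0.408). No member passed over all genes and 1 fell when adjusted over the list alone. Gnl3 and Ncl, which encode nucleolar proteins, differed by -0.44 and -0.28 with adjusted p-values of 0.101 and 0.169.

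Proliferation and leukaemia programmes gave no list call by camera on the quantile-normalized values. List adjusted p-values were 0.509 for S-phase genes, 0.211 for G2/M genes (0.0210 without quantile normalization), 0.898 for B-lymphoid progenitor genes, 0.341 for STAT5 and BCR-ABL signalling targets and 0.433 for NF-kB targets, and none of their members passed. Among p53 targets (0.680) Fas rose and 19 of 20 members did not pass. Oxidative phosphorylation genes (0.262), unfolded protein and integrated stress response genes (0.435), immediate early and heat shock genes (0.433), cytosolic ribosomal proteins (0.672) and adhesion and bone marrow homing genes (0.262) had no member that passed. Among 19 measured glycolysis and hypoxia genes, Egln3 fell and 18 did not pass (0.509).

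**Figure D2:**
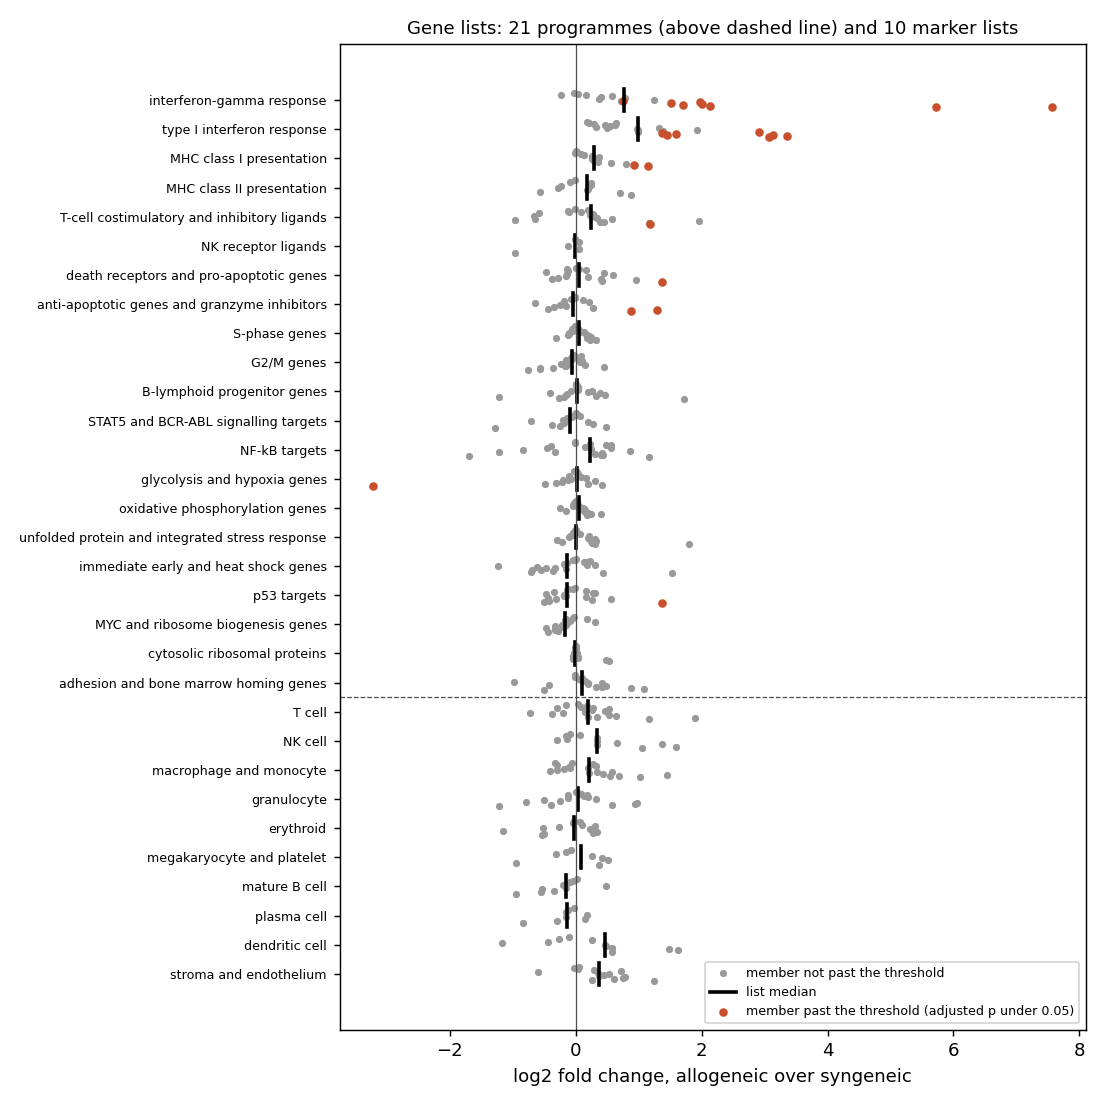
Log2 fold change (horizontal axis, allogeneic over syngeneic) of each measured member of the 31 gene lists, with members past an adjusted p of 0.05 in orange, the others in grey and a black bar at each list's median; the dashed line parts the 21 programmes from the 10 marker lists. The interferon-gamma and type I interferon lists had medians of 0.77 and 0.99, and no marker list held a member past the threshold.

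Egln3 led the 12 largest falls by limma, and several of the others were near background. Rflnb, a refilin gene, fell by 1.31 on the log2 scale (SE 0.19, adjusted p = 0.0131). Cd302, a C-type lectin receptor gene, fell by 1.22 (SE 0.20, adjusted p = 0.0317), and Slc17a9, a vesicular nucleotide transporter gene, fell by 1.02 (SE 0.16, adjusted p = 0.0226). Rbm4b, an RNA-binding protein gene, fell by 0.96 (adjusted p = 0.0426) and 3300002A11Rik fell by 0.84 (adjusted p = 0.0387). Ppp4r1l-ps fell by 1.01, but 5 of its 8 probe sets had the opposite sign. Slc35d3 and Atp2b4, which encode a sugar transporter and a plasma membrane calcium pump, were at least 1.77-fold and at least 1.37-fold lower. Agr2, a protein disulfide isomerase gene, exceeded background on 1 of 10 arrays and has no bound on its fold. Ccer1 and Vgll2 were not well above background in either group.

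Allogeneic profiles were as far from each other as from the syngeneic ones. Mean distances were 121 within the allogeneic group, 118 between groups and 90.9 within the syngeneic group. Allogeneic animals 2 and 4 were the closest allogeneic pair. The SD of their log2 differences was 0.315 over the 10455 genes above background on every array, against 0.455 to 0.668 in the other allogeneic pairs. Over both groups the mean distance between exceeded that within by 11.3 (one-sided exact permutation p = 0.00794, the smallest that 126 splits can give). Leaving out any 1 syngeneic array brought the exact p to between 0.0635 and 0.0714. By chance 0.794% of genes would have groups without overlap, and 4.83% did (879 genes). The number of called genes, 106, became 59, 55 and 57 without syngeneic animals 1, 2 and 5, 68 without allogeneic animal 4, 630 without allogeneic animal 1, and 649 without allogeneic animals 1, 3 and 4 together.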

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

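The tests of other cell types, of allogeneic animal 1 and of the spread from neighbouring genes were chosen only after the results were seen, as were the chromosome segment test and the removal of the arrays of raised low end as an alternative setting. Among 62 groups of 5 animals tested for a sample far from the rest, chance would give about 1 in 20. Syngeneic animal 3 stood above its group for Rtp4, at 8.78 against 6.81 to 7.36 on the log2 scale, and for Ifit1bl1, at 8.35 against 7.35 to 7.56. Allogeneic animal 3 stood below its group for Zbp1, at 10.9 against 11.6 to 11.8. Allogeneic animal 2 stood above its group for Agr2, at 3.76 against 0.82 to 1.65, all below background. Of 10092 probe sets with no or several symbols, which the gene comparison did not use, 67 passed limma's test, 30 higher and 37 lower. The 9 of these with several symbols were all higher in the allogeneic group.

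The first pattern is the higher level of interferon-inducible genes in allogeneic leukaemia. Chance assignment was argued against for the gene count if the animals are independent. Only the real one, 1 of 100 splits of the samples, reached 106 genes and the highest other gave 1. The splits cannot exclude a chance difference between leukaemia lines, since animals of a group may have shared an earlier recipient. Chance assignment could not be excluded for the number of gene lists, since 18 of 100 splits gave as many as the real 4 lists. The highest other gave 6, though 14 of the other 17 swap only 1 animal per group and so keep most of the real contrast. Neither the raised low end of 3 arrays nor quantile normalization accounted for it, since the interferon-gamma list median of 0.77 was 0.82 without those arrays and 0.77 on log2 values as deposited. Cells of another type in the sort cannot be told apart from a change within the leukaemia in the allogeneic environment, which may be the biological explanation. The reason is that stroma and endothelium markers above background had a median of 0.44, over the bound of 0.38 set from the interferon-gamma list. That list did not pass (adjusted p = 0.0754 by camera), and its median levels were near background.

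The second pattern is allogeneic animal 1, without which 630 genes were called. Over 10455 genes, its deviation from the syngeneic level correlated at 0.17 with that of the other 4 allogeneic animals, against 0.38 to 0.56 for each of those, with separate syngeneic animals behind each side so that 0 is expected without a shared change. A raised low end was argued against, since leaving out allogeneic 3 or 4, which share it, gave at most 91 genes. More myeloid RNA in the other 4 sorts was argued against for the 254 newly called genes that fell (median -0.78, smallest fall -0.41), since it would lower leukaemia genes alike, yet 22 B-lymphoid progenitor genes had a median of 0.014 (SD 0.59) and only Pax5 fell that far. For the 271 that rose it cannot be told apart from a change in the leukaemia, as macrophage and monocyte markers had a median of 0.43 without this animal, and a different history of that leukaemia line was not tested.

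The third pattern is that called genes lay next to each other in the order of genes of the GRCm38.p6 annotation. There were 9 adjacent pairs among the 106 called genes against a mean of 0.612 in random draws (permutation p = 1e-05, the smallest that 100000 draws can give). All but Dgcr6 with Prodh and Psmb9 with Tap1 join genes of related families, whose probes may cross-hybridise. Dgcr6 and Prodh are unrelated neighbours that rose by 2.13 and 2.41, and a gain of their chromosome segment was argued against by the 10 nearest measured genes above background, whose median change was -0.061, while their control by a shared element was not tested. Spread from interferon-induced neighbours cannot be told apart from these family relations: of 77 risen genes outside the interferon lists, 3 (Gm12185, Gm4951 and BC023105) lay within 5 genes of one of the 15 list genes that passed, against a mean of 0.505 in random draws (permutation p = 0.014), and all 3 belong to the pairs above.

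The test of other cell types at first left out the stroma and endothelium list, and the next highest list, of dendritic cell markers, had a median of 0.37. Comparisons of intensity gains between marker and interferon probe sets were also tried and dropped, because levels of different probe sets cannot be set against each other. The test of spread at first left out the genes of the adjacent pairs and counted list genes that had not passed. A test written beforehand, on 4 called genes at background in both groups, gave a median size of 1.33 without the arrays of raised low end against 1.34 with them.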

How the results depend on the processing

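The log2 values without quantile normalization, 32 added, genes at background left out and the arrays of raised low end left out were settings chosen after seeing the data. The gene count of 106 (92 rose, 14 fell) became 185 (122 and 63) over all probe sets, 237 and 269 with the lower 25% and 50% of genes left out, 280 with an intensity trend, 720 (424 and 296) with array weights, 296 with 32 added, 195 without genes at background, 649 (389 and 260) without allogeneic animals 1, 3 and 4, and 360 at adjusted p under 0.1. It stayed within 1.5 times at 127 (109 and 18) without quantile normalization, 72 with median centring, 71 with the mean of probe sets, 93 with robust eBayes and 103 with a 1.5-fold change required. Single arrays left out gave 55 to 630 genes, with 59, 55 and 57 without syngeneic 1, 2 and 5, 68 without allogeneic 4 and 630 (362 and 268) without allogeneic 1. The cause of these changes in the count was not tested, apart from the count without allogeneic animal 1. Lists called were 2 with an estimated correlation and 8 with fry, which does not compare a list with other genes, and 4 to 6 elsewhere. The separation of 11.3 ran from 6.79 to 17.5 with 1 array left out, and its exact p rose to between 0.0635 and 0.0714 without any 1 syngeneic array. Animal numbers do not pair the samples: same-number deviations correlated between -0.21 and 0.35, and 2 of 5 samples correlated best with their own number. With the replicate block 14 genes were called (14 higher, 0 lower), 4 lists kept their call, and swaps within numbers gave a separation of 11.3 with p = 0.0625, the smallest that exact test can give. Not every named gene was followed over the settings. Those followed were the 12 largest rises and falls, the called members among the 4 of smallest p per list, and Cdkn2a, Abl1 and Bcr. Of these, none past the threshold reversed, and no called list did. However, 3300002A11Rik lost its call under 14 settings, Serpinb9 under 13, Vgll2, Ccer1 and Rbm4b under 12 each, and Agr2 and Tap1 under 11 each. Oasl2 and Slc17a9 lost theirs under 9 each, Cd302 under 8 and Serpinb6b under 6. Genes near background are limited by signal, so their fold changes depend most on the scale.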

Other observations

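The genes in both paragraphs were chosen after their values were seen. Beyond the fixed lists, several called genes encode proteins of immune recognition and cell death. Il12rb1, a subunit of the interleukin-12 receptor, rose by 2.10 on the log2 scale (SE 0.16, 5 animals per group, limma adjusted p = 0.000302). Tnfsf10, which encodes the death ligand TRAIL, rose by 2.56 (SE 0.23, adjusted p = 0.000763). Casp1 and Gsdmd, an inflammatory caspase and the pore-forming protein it cleaves, rose by 0.90 (SE 0.15, adjusted p = 0.0309) and 0.66 (SE 0.12, adjusted p = 0.0477). Among MHC class I related genes outside the lists, Tapbpl, a peptide editor, rose by 1.56 (SE 0.11, adjusted p = 0.000233), H2-M3 by 1.01 (SE 0.13) and H2-Q5 by 1.85 (SE 0.26). Rasgrp1, an activator of Ras, fell by 0.80 (SE 0.11, adjusted p = 0.0120), with 1 of its 4 probe sets of opposite sign.

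Genes best known from other tissues were also called. Prodh, the mitochondrial enzyme that begins proline breakdown, rose by 2.41 (SE 0.16, adjusted p = 0.000233) and was above background on all 10 arrays. Tnp2 and Prm1, which encode sperm chromatin proteins, rose by 2.21 (SE 0.32) and 0.71 (SE 0.12), and Insl6, a relaxin family gene, rose by 1.65 (SE 0.27). Tnp2 exceeded background on 2 of 5 syngeneic and 5 of 5 allogeneic arrays. In gene order Tnp2 and Prm1 lay within 5 genes of Socs1, Tnp2 also of Ciita, and Insl6 lay within 5 genes of Cd274. These neighbours are members of the interferon-gamma response list that did not pass over all genes. Of the 77 risen genes outside the interferon lists, 8 lay within 5 genes of any of 40 interferon-list genes. The number expected by chance is not given here, so no link is drawn from these positions. Sln, which encodes the muscle calcium pump regulator sarcolipin, rose by 0.78 (SE 0.11) from a syngeneic mean of 12.19.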
